A study of Mus musculus with 55 samples.

How the data were processed

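The cortex of 55 mice was measured on an nCounter panel of 799 genes, in 8 groups of diet (vehicle or PLX5622) and injury (naive, or 1, 7 or 30 days after TBI), with 1 library per mouse. Groups were taken from the sample labels. One naive vehicle mouse (695) carries 7d in its title, but its injury label says naive, and it was placed among naive vehicle mice. Mouse numbers are animal identities and link no mice across groups. Days on the diet of the naive mice are not given in the sources used here, and there is 1 naive PLX5622 group for all days, so time on the diet goes with the day after injury.

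Per the labels' protocols, brains were snap-frozen and cut into alternating thin and thick sections. Regions of thick sections were picked on neighbouring thin sections stained for CD11b, where microglia were hypertrophied or rod-shaped, and RNA was extracted with a low-input kit. Pre-amplification cycles were set from Gapdh and Actb, per the labels' protocols, and the number of cycles per mouse is not given in the sources used here. The deposited values are a signal that is never negative: barcode counts divided by 1 size factor per sample, on a linear scale. DESeq2 is the tool that the submitters' processing notes name, with no version, and the background step is not given in the sources used here. In each of the 55 samples 1 of 9 reference genes sits at a value fixed for that gene, at a tolerance of 3e-06 narrowed after seeing the data (54 of 55 at 1e-04), as a median of ratios over those 9 genes would leave it. Whole counts were recovered for 100% of values in every sample, at a tolerance of 0.02, by dividing by the value of 1 count. Every gene symbol matched a RefSeq gene, 792 by current symbol and 7 by a synonym. No 2 mice of a group had counts that agree within sampling noise (lowest chi-square per degree of freedom 5.2).

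The total count per mouse ran from 176038 to 1208609, a ratio of 6.87, and its median per nCounter cartridge from 342217 to 916735 over 5 cartridges. The design was fixed before the data were examined, with the group table, the gene lists, the rule for named genes and most alternatives. It expected either normalised values or raw counts, and the values are normalised, so limma 3.58.1 in R 4.3.3 was used: lmFit and eBayes with a trend on log2(value + 1), with 8 group means and the cartridge as covariate, all 55 mice in 1 fit. P-values were adjusted by Benjamini-Hochberg over 799 genes in each comparison, with a threshold of 0.05, in two-sided tests. Fold changes on that scale understate changes of low genes. A background level was read from 20 genes picked after seeing the data, with median 6.76 and a level of 15.4 that 95% of their values stay below.

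Comparisons were TBI against naive within each diet and day, PLX5622 against vehicle at each day and without injury, 7 against 1 day and 30 against 7 days on vehicle, and the interaction of diet and injury at each day, 15 in all. Gene lists written from textbook knowledge were tested with camera, preset correlation 0.01, and again with an estimated correlation, adjusted over the 22 lists that had at least 4 measured members. A camera test compares a list with the other genes of a targeted panel. The lists covered microglia, border macrophages and infiltrating leukocytes, astrocytes, reactive astrocytes, oligodendrocytes and myelin, endothelium and pericytes, pan-neuronal genes, synaptic vesicles and release, glutamate signalling, GABA and interneurons, monoamines and acetylcholine, activity-regulated and CREB genes, inflammatory cytokines and NF-kB, interferon response and antigen presentation, complement, apoptosis and cell stress, oxidative stress defence, lysosome and autophagy, growth factors and vascular remodelling, axon guidance and cytoskeleton, neurodegeneration-associated genes and the panel's reference genes. One more list, for oligodendrocyte precursors, had 2 measured members and was not tested. Of 68 calls of a list, 14 held with an estimated correlation. These were the microglia and complement lists between diets without injury and at 1 and 7 days, the microglia list between diets at 30 days, both lists at 30 days on PLX5622 and in the interaction at 30 days, the reactive astrocyte list at 1 day in each diet and the interferon list at 7 days on vehicle.

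Named genes follow a rule: for each comparison, the 8 largest rises and the 8 largest falls among called genes, for an interaction the 8 smallest adjusted p among called genes, up to 4 members with the smallest p of each list called, and always Csf1r, Cx3cr1, P2ry12, Tmem119, Aif1, Itgam, Cd68, Trem2, Gfap and C4a. The text names fewer of these, and some results are not reported here.

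Alternatives changed 1 choice at a time: the covariate (none, RNA extraction batch with 3 levels, or both batches), centring on the sample median or on reference genes, leaving out genes of low mean, a pseudocount of 10, eBayes without a trend or robust, a fit on the compared groups alone, DESeq2 1.42.0 on the recovered counts and each mouse left out in turn. Chosen after seeing the data were edgeR 4.0.16 with its quasi-likelihood test on the recovered counts (774 genes kept), a limma fit with a weight per group, fits without the 3 libraries under 300000 counts, and the gene list tests with each mouse left out. Limma was tested on simulated counts with 200 of 799 genes changed and may recover less with fewer. For vehicle mice at 1 day against naive it recovered 61.8% of genes changed 1.5-fold, 86.6% at 2-fold and 97% at 3-fold, with 3.37% false calls, and for the 30 day interaction 30.7%, 72.5% and 88.2%. With the lysosome and autophagy list raised 1.5-fold in that first comparison, it was called in 5 of 5 simulated sets. Simulated sets with no change had a mean of 0 called lists, and splits of the real mice (below) a median of 1. Simulation may understate false list calls. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.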

Results

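Expression of 799 genes was measured with the nanoString nCounter, which counts barcoded probes bound to single RNA molecules, in the cortex of 55 adult male C57BL/6 mice, 1 library per mouse. Mice ate a vehicle diet or the same chow with PLX5622, an inhibitor of the CSF1 receptor on which microglia depend, at 1200 mg/kg for 14 days before a diffuse traumatic brain injury (TBI) and until tissue was taken. The vehicle diet had 7 naive mice and 6, 7 and 5 mice at 1, 7 and 30 days after TBI, and the PLX5622 diet had 6 naive mice and 8, 9 and 7 mice at those days. RNA came from regions chosen on neighbouring sections stained for CD11b, the product of Itgam. Itgam is thus no finding between regions and its values are given for description. It is still counted in the microglia and complement lists. The choice of regions may bear on these whole lists on either diet, which was not tested. Total counts per mouse, recovered from the normalised values, had a median of 519047. Group medians (naive, 1, 7 and 30 days) were 504376, 528121, 604862 and 536543 on vehicle and 616932, 424759, 442427 and 505694 on PLX5622. Levels are normalised counts (mean ± SD), fold changes are on the log2(value + 1) scale with their SE, and a gene is called at an adjusted p under 0.05 in limma. Counts of mice beside a gene or list say how many mice of the group lay beyond the median of the group compared, in the direction given.

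The first question was what the diet did without injury. In naive mice on PLX5622, 27 genes were lower and 0 higher than in naive mice on vehicle (limma, with 75 genes lower and 0 higher at an unadjusted p under 0.05, 27 called by DESeq2 and 25 by edgeR). Genes of microglia, the resident macrophages of the brain, led the fall. P2ry12, a purinergic receptor of microglia, changed by -4.82 ± 0.27 (6 of 6 mice, adjusted p = 8.0e-21). Cx3cr1, the fractalkine receptor, changed by -5.13 ± 0.34 (adjusted p = 8.6e-18) and Csf1r, the drug's target, by -4.37 ± 0.37 (adjusted p = 1.0e-13), each in 6 of 6 mice. Csf1r stood at 198 ± 21.4 normalised counts on vehicle (n = 7) and 8.77 ± 3.64 on PLX5622 (n = 6). The 3 chains of complement C1q, which starts the classical pathway, changed by -5.59 (C1qb), -5.31 (C1qa) and -5.09 (C1qc). Smaller falls were measured for Fcrls (-2.91 ± 0.48), Trem2, a lipid-sensing receptor of microglia (-2.57 ± 0.37), Tmem119 (-2.27 ± 0.18) and Cd68, a lysosomal protein of phagocytes (-1.56 ± 0.32). Itgam changed by -4.71 ± 0.46. Gfap, the intermediate filament of astrocytes, was not called (0.29 ± 0.57, adjusted p = 0.856, higher in 5 of 6 mice), nor were Aif1 (-0.30 ± 0.25) and C4a (-0.10 ± 0.25), whose probe target is nearly identical to C4b and whose value is uncertain for that reason.

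The microglia list fell (median log2 fold change -2.21, 6 of 6 mice, adjusted p = 1.2e-68, adjusted p = 8.7e-08 with an estimated correlation). Among the 23 members measured, 0 were higher, 18 lower and 5 not called, and 0 higher and 20 lower adjusted over the list alone. The complement list fell (median log2 fold change -3.37, 6 of 6 mice, adjusted p = 1.5e-13, adjusted p = 1.6e-04 with an estimated correlation). Of its 8 measured members, 0 were higher, 5 lower and 3 not called, and 0 higher and 5 lower adjusted over the list alone. The 5 complement members called are also in the microglia list, and the 3 others had a median of -0.19. Within extraction batches 1, 2 and 3 the microglia list mean differed by -2.43, -2.85 and -2.73. On PLX5622, 21 of the 23 microglia genes had a mean under 15.4, a level that 95% of the values of 20 genes known mainly from other tissues stayed below, against 5 of 23 on vehicle, where fold changes understate differences. Those 20 genes were picked after the values had been seen.

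**Figure D1:**
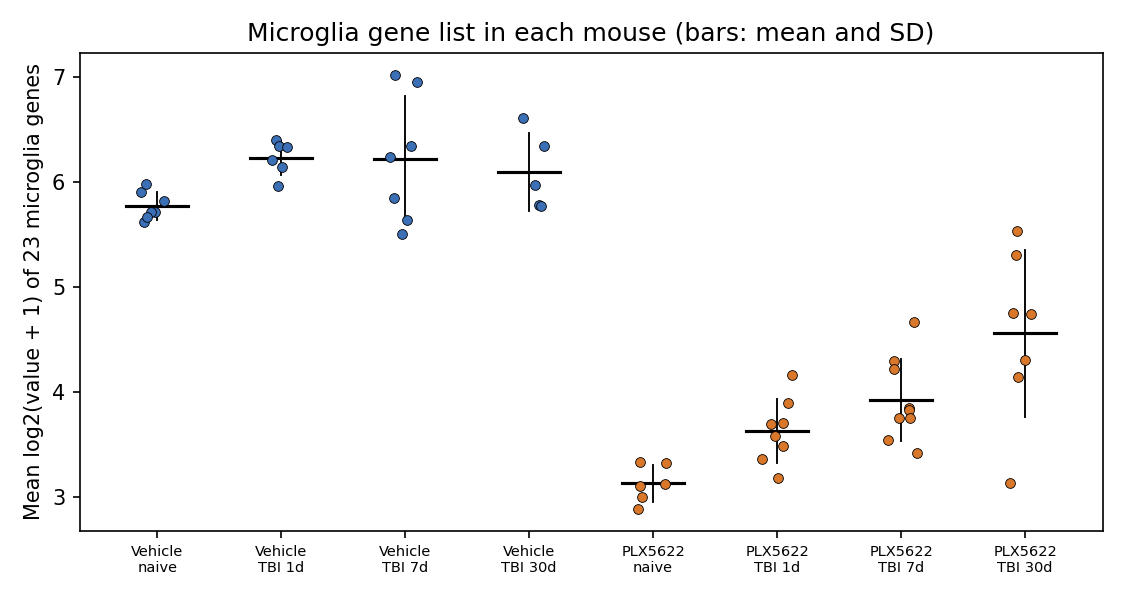
Mean log2(value + 1) of the 23 microglia genes in each mouse (vertical axis, log2 scale) for the 8 groups (horizontal axis), where points are mice and bars show the mean and SD. Naive mice lay at 5.77 ± 0.13 on vehicle and 3.13 ± 0.18 on PLX5622, and PLX5622 mice at 30 days at 4.56 ± 0.80.

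Injury on the vehicle diet was followed at 1, 7 and 30 days. At 1 day after TBI, 15 genes were higher and 3 lower than in naive vehicle mice, with 104 at an unadjusted p under 0.05. Ccl12, a chemokine that attracts monocytes, rose by 3.15 ± 0.57 in 6 of 6 mice (adjusted p = 4.8e-04), from 8.53 ± 2.56 to 92.1 ± 70.3 normalised counts. Gfap rose by 2.83 ± 0.60 in 6 of 6 mice (adjusted p = 0.00376), from 346 ± 108 (n = 7) to 2367 ± 1039.9 (n = 6). Cd44, the hyaluronan receptor, rose by 2.21 ± 0.47, Lox, which cross-links collagen, by 2.09 ± 0.36, and Tnfrsf1a, a TNF receptor, by 1.46 ± 0.32. Msn, which ties membrane to actin, rose by 1.35 ± 0.31, Hmox1, which breaks down heme, by 1.51 ± 0.41 and the cytokine Tnf by 1.35 ± 0.38. Lower were Egr1, an activity-regulated transcription factor (-1.38 ± 0.38, 6 of 6 mice), Mfge8, which bridges dying cells to phagocytes (-0.70 ± 0.16, 6 of 6 mice), and Stx1a, a synaptic membrane-fusion protein (-0.56 ± 0.13, 6 of 6 mice). Of the microglial genes always looked at, Csf1r (0.11 ± 0.39), Cx3cr1 (0.41 ± 0.35), P2ry12 (-0.56 ± 0.28) and Tmem119 (0.03 ± 0.19) were not called.

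Of the lists, the reactive astrocyte call held with both correlations. The reactive astrocyte list rose (median log2 fold change 0.81, 6 of 6 mice, adjusted p = 3.9e-10, adjusted p = 0.03 with an estimated correlation). Among the 10 members measured, 3 were higher, 0 lower and 7 not called, and 8 higher and 0 lower adjusted over the list alone. The members called were Gfap, Cd44 and Tspo. Members of the inflammatory cytokine and NF-kB list rose as a set (median log2 fold change 0.55, 6 of 6 mice, adjusted p = 1.9e-10, adjusted p = 0.0642 with an estimated correlation). Of its 37 measured members, 4 were higher, 0 lower and 33 not called, and 14 higher and 1 lower adjusted over the list alone. The microglia list rose (median log2 fold change 0.39, 6 of 6 mice, adjusted p = 3.7e-04, adjusted p = 0.366 with an estimated correlation). For the interferon response and antigen presentation list the test gave a rise (median log2 fold change 0.79, 6 of 6 mice, adjusted p = 0.00184, adjusted p = 0.316 with an estimated correlation). The complement list rose (median log2 fold change 0.68, 6 of 6 mice, adjusted p = 0.0194, adjusted p = 0.316 with an estimated correlation). The 3 complement members outside the microglia list had a median of -0.033, the opposite sign. In these 3 lists limma called 0 members, with at most 2 per list adjusted over the list alone, at most 6 in one direction at an unadjusted p under 0.05, at most 3 called by DESeq2 and at most 3 by edgeR. As a set, activity-regulated and CREB genes fell (median log2 fold change -0.13, 5 of 6 mice, adjusted p = 0.00138, adjusted p = 0.316 with an estimated correlation). Among the 35 members measured, 0 were higher, 1 lower and 34 not called, and 0 higher and 2 lower adjusted over the list alone. For the synaptic vesicle and release list the test gave a fall (median log2 fold change -0.21, 6 of 6 mice, adjusted p = 0.00156, adjusted p = 0.316 with an estimated correlation). Of its 18 measured members, 0 were higher, 1 lower and 17 not called, and 0 higher and 1 lower adjusted over the list alone. The glutamate signalling list fell (median log2 fold change -0.12, 6 of 6 mice, adjusted p = 0.0194, adjusted p = 0.316 with an estimated correlation). In this list limma called 0 members, with 0 adjusted over the list alone, 0 in its direction at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by edgeR.

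Within extraction batches 1, 2 and 3 Gfap differed by 2.86, 2.39 and 3.07, Ccl12 by 4.00, 1.64 and 3.93 and Cd44 by 2.74, 0.45 and 2.71. DESeq2 called 38 genes and edgeR 40, and the count was 9 without any 1 of mice 697, 732 and 741, 11 without any 1 of mice 714, 726 and 737 and 28 without mouse 704. The call of Stx1a was lost without mouse 741 (adjusted p = 0.0561), of Egr1 without any 1 of mice 691, 695, 697, 706, 714 and 720 (adjusted p from 0.052 to 0.114), of Hmox1 without any 1 of mice 691, 697, 706, 726, 732, 737, 741 and 742 (adjusted p from 0.052 to 0.133) and of Tnf without any 1 of mice 695, 697, 714, 726, 732, 737, 741 and 742 (adjusted p from 0.0646 to 0.218). With no covariate Egr1 (adjusted p = 0.188), Msn (adjusted p = 0.0931) and Tnf (adjusted p = 0.053) were not called (ranges 0.03 to 0.188 over 6 alternatives, 0.001 to 0.0931 over 6 alternatives and 0.0364 to 0.053 over 5 alternatives). The call of Tspo, in the reactive astrocyte list, was lost without any 1 of mice 691, 697, 706, 720, 726, 732, 737, 741 and 742 (adjusted p from 0.0536 to 0.153). At 1 day on vehicle, camera no longer called the complement list without mouse 704 (adjusted p = 0.0523).

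**Figure D2:**
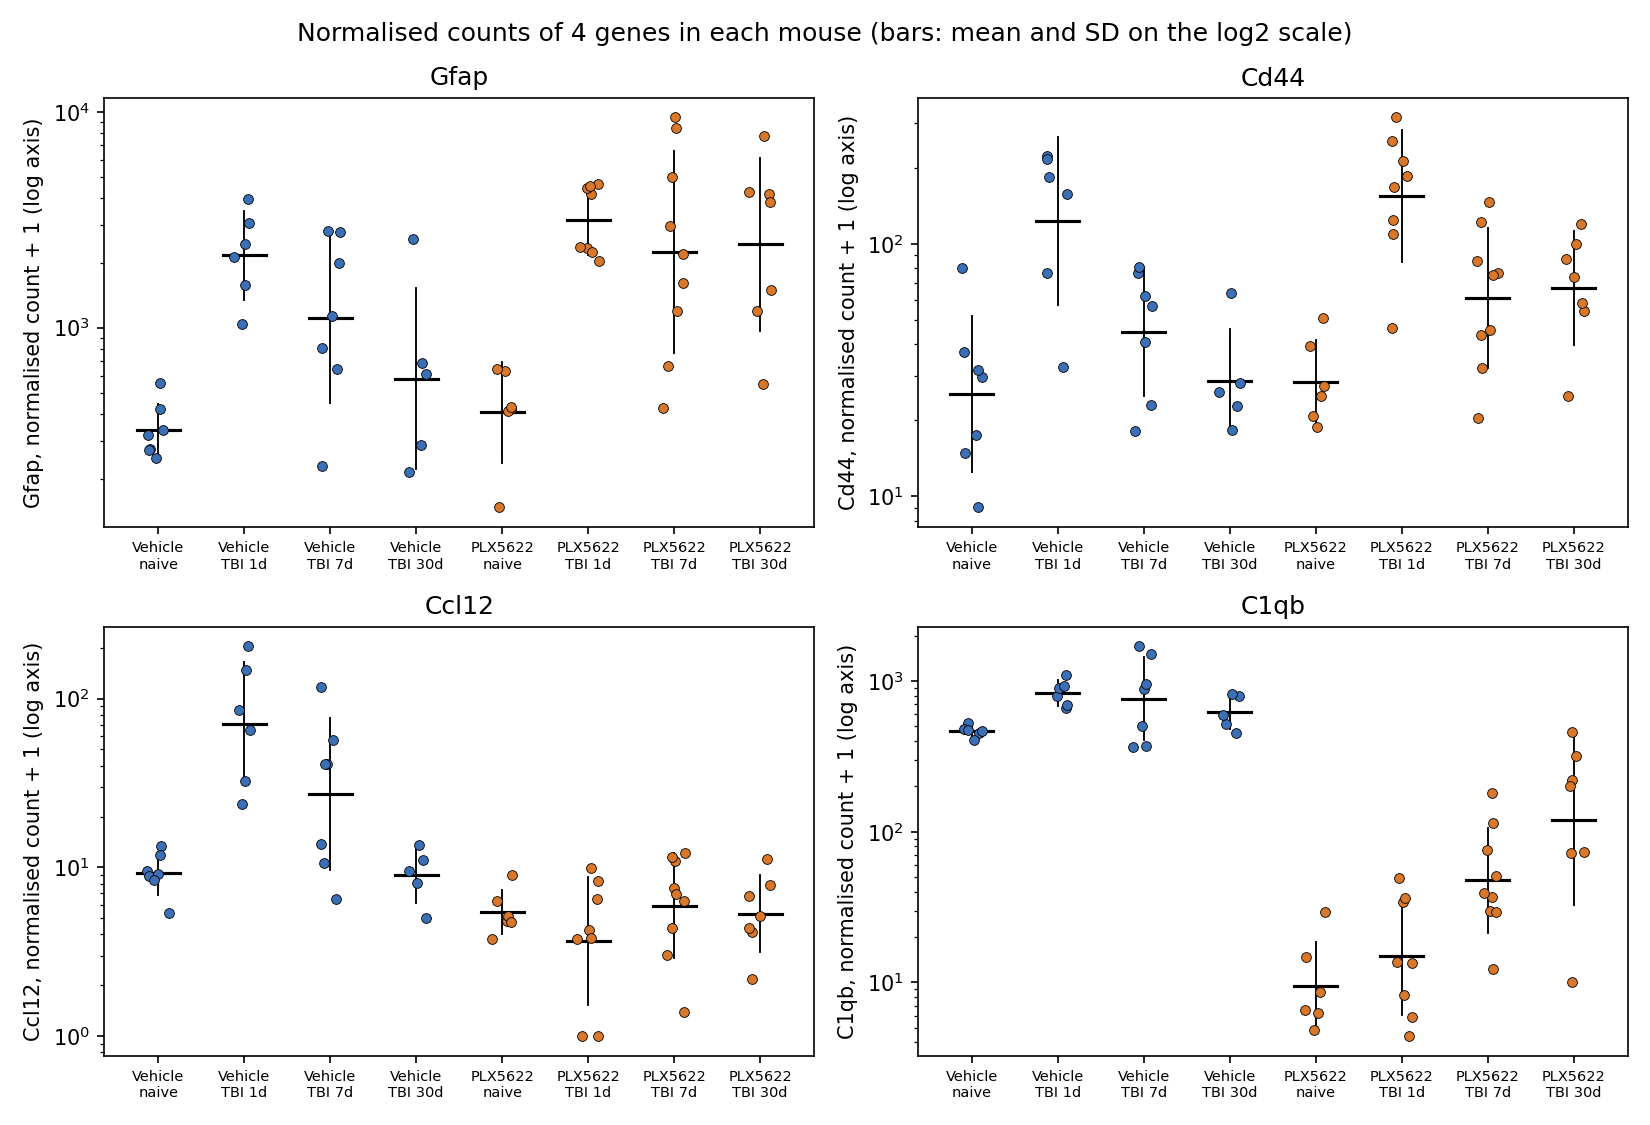
Normalised count + 1 (vertical axes, log scale) of Gfap, Cd44, Ccl12 and C1qb in each mouse of the 8 groups (horizontal axes), where points are mice and bars show the mean and SD on the log2 scale. Gfap lay at 2367 ± 1039.9 on vehicle and 3343 ± 1184 on PLX5622 at 1 day, and C1qb at 10.8 ± 9.37 in naive and 192 ± 158 in 30 day mice on PLX5622.

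At 7 days on vehicle, limma called 0 of the 799 genes, with 29 higher and 22 lower at an unadjusted p under 0.05, 10 called by DESeq2 and 9 by edgeR. Cxcl10, an interferon-induced chemokine, had the value 2.58 ± 0.61 (adjusted p = 0.0636, 6 of 7 mice) and Irf7, a transcription factor of the interferon response, 1.49 ± 0.41 (adjusted p = 0.113). Gfap had 1.69 ± 0.55 (adjusted p = 0.349, 6 of 7 mice), with extraction batch values of 2.73, 2.02 and 1.16. The interferon call held with both correlations. The interferon response and antigen presentation list rose (median log2 fold change 0.88, 6 of 7 mice, adjusted p = 1.8e-12, adjusted p = 0.00278 with an estimated correlation). Among the 5 members measured, 0 were higher, 0 lower and 5 not called, and 5 higher and 0 lower adjusted over the list alone (limma, where 5 lay higher and 0 lower at an unadjusted p under 0.05, with 3 called by DESeq2 and 3 by edgeR). The inflammatory cytokine and NF-kB list rose (median log2 fold change 0.29, 7 of 7 mice, adjusted p = 6.3e-11, adjusted p = 0.0599 with an estimated correlation). Of its 37 measured members, 0 were higher, 0 lower and 37 not called, and 5 higher and 0 lower adjusted over the list alone (limma, where 7 lay higher and 2 lower at an unadjusted p under 0.05, with 4 called by DESeq2 and 3 by edgeR). The microglia list rose (median log2 fold change 0.43, 5 of 7 mice, adjusted p = 8.5e-09, adjusted p = 0.187 with an estimated correlation). Members of the reactive astrocyte list rose as a set (median log2 fold change 0.23, 6 of 7 mice, adjusted p = 0.00502, adjusted p = 0.313 with an estimated correlation). As a set, complement genes rose (median log2 fold change 0.63, 5 of 7 mice, adjusted p = 0.0066, adjusted p = 0.297 with an estimated correlation). The 3 complement members outside the microglia list had a median of -0.016, the opposite sign. The astrocyte list rose (median log2 fold change 0.15, 6 of 7 mice, adjusted p = 0.00971, adjusted p = 0.313 with an estimated correlation). Members of the activity-regulated and CREB list fell as a set (median log2 fold change -0.15, 4 of 7 mice, adjusted p = 0.00971, adjusted p = 0.386 with an estimated correlation). Members of the synaptic vesicle and release list fell as a set (median log2 fold change -0.13, 6 of 7 mice, adjusted p = 0.024, adjusted p = 0.386 with an estimated correlation). As a set, monoamine and acetylcholine genes fell (median log2 fold change -0.24, 7 of 7 mice, adjusted p = 0.0496, adjusted p = 0.313 with an estimated correlation). In these 7 lists limma called 0 members, with at most 1 per list adjusted over the list alone, at most 3 in one direction at an unadjusted p under 0.05, at most 1 called by DESeq2 and at most 1 by edgeR.

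The count of genes at 7 days on vehicle was 3 without mouse 730, 4 without mouse 718 and 8 without mouse 724. Cxcl10 was called with the extraction batch as covariate (adjusted p = 0.0323) and with centring on the sample median (adjusted p = 0.0232) or on the reference genes (adjusted p = 0.0245), and Irf7 with centring on the sample median (adjusted p = 0.0483). Ranges of adjusted p were 0.0232 to 0.0855 over 5 alternatives (Cxcl10) and 0.0483 to 0.0997 over 5 alternatives (Irf7). At 7 days on vehicle, camera no longer called the synaptic vesicle and release list without mouse 702 or 706 (adjusted p = 0.132 and 0.0524) and the monoamine and acetylcholine list without any 1 of mice 691, 702, 710, 714, 718, 730, 732, 735 and 742 (adjusted p from 0.0507 to 0.117).

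At 30 days on vehicle, limma called 0 of the 799 genes, with 20 higher and 9 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by edgeR. Gfap had the value 0.76 ± 0.62 (adjusted p = 0.993, 3 of 5 mice), and its extraction batch values were -0.98, 0.55 and 3.11, which differ in sign. Csf1r (0.35 ± 0.40), Cx3cr1 (0.30 ± 0.36), P2ry12 (0.22 ± 0.29) and Trem2 (0.43 ± 0.40) were not called. The endothelial and pericyte list rose (median log2 fold change 0.31, 4 of 5 mice, adjusted p = 7.5e-05, adjusted p = 0.412 with an estimated correlation). Its members include Eng, a TGF-beta co-receptor of vessels (0.48 ± 0.18), and Tie1, an endothelial receptor kinase (0.42 ± 0.20). The oligodendrocyte and myelin list fell (median log2 fold change -0.18, 2 of 5 mice, adjusted p = 0.00317, adjusted p = 0.988 with an estimated correlation). In these 2 lists limma called 0 members, with 0 per list adjusted over the list alone, at most 3 in one direction at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by edgeR. The count of genes was 1 without any 1 of mice 716, 722 and 737. At 30 days on vehicle, camera no longer called the oligodendrocyte and myelin list without mouse 684 or 695 (adjusted p = 0.718 and 0.102).

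Later days were also set against earlier ones on the vehicle diet. From 1 to 7 days, limma called 0 of the 799 genes, with 19 higher and 47 lower at an unadjusted p under 0.05, 15 called by DESeq2 and 9 by edgeR. Stat3, a transcription factor of reactive glia, had -0.82 ± 0.23 (adjusted p = 0.11), Cd44 -1.53 ± 0.45 (adjusted p = 0.134) and Gfap -1.14 ± 0.58 (adjusted p = 0.626, lower in 5 of 7 mice). The reactive astrocyte list fell (median log2 fold change -0.65, 7 of 7 mice, adjusted p = 1.9e-06, adjusted p = 0.188 with an estimated correlation). Among the 10 members measured, 0 were higher, 0 lower and 10 not called, and 0 higher and 4 lower adjusted over the list alone (limma, where 0 lay higher and 7 lower at an unadjusted p under 0.05, with 3 called by DESeq2 and 2 by edgeR). From 7 to 30 days, limma called 0 of the 799 genes, with 60 higher and 11 lower at an unadjusted p under 0.05, 2 called by DESeq2 and 4 by edgeR. Nos2, the inducible nitric oxide synthase, had -1.52 ± 0.38 (adjusted p = 0.142) and Cxcl10 -2.21 ± 0.66 (adjusted p = 0.43). Members of the interferon response and antigen presentation list fell as a set (median log2 fold change -0.66, 5 of 5 mice, adjusted p = 3.8e-07, adjusted p = 0.064 with an estimated correlation). Of its 5 measured members, 0 were higher, 0 lower and 5 not called, and 0 higher and 3 lower adjusted over the list alone (limma, where 0 lay higher and 3 lower at an unadjusted p under 0.05, with 2 called by DESeq2 and 3 by edgeR). Camera placed the inflammatory cytokine and NF-kB list below other panel genes (median log2 fold change -0.09, 4 of 5 mice, adjusted p = 1.2e-04, adjusted p = 0.517 with an estimated correlation). Among the 37 members measured, 0 were higher, 0 lower and 37 not called, and 0 higher and 2 lower adjusted over the list alone (limma, where 0 lay higher and 4 lower at an unadjusted p under 0.05, with 1 called by DESeq2 and 2 by edgeR). The microglia list fell (median log2 fold change -0.17, 3 of 5 mice, adjusted p = 0.00157, adjusted p = 0.54 with an estimated correlation). For the reactive astrocyte list the test gave a fall (median log2 fold change -0.16, 4 of 5 mice, adjusted p = 0.00614, adjusted p = 0.54 with an estimated correlation). The complement list fell (median log2 fold change -0.28, 4 of 5 mice, adjusted p = 0.0129, adjusted p = 0.517 with an estimated correlation). Its 3 members outside the microglia list had a median of -0.26. As a set, endothelial and pericyte genes rose (median log2 fold change 0.35, 5 of 5 mice, adjusted p = 0.0148, adjusted p = 0.54 with an estimated correlation). In these 4 lists limma called 0 members, with 0 per list adjusted over the list alone, at most 4 in one direction at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by edgeR.

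The count from 1 to 7 days was 1 without mouse 702 and 11 without mouse 704, and from 7 to 30 days 1 without any 1 of mice 707, 716 and 724.  From 7 to 30 days, camera no longer called the microglia list without mouse 684 or 686 (adjusted p = 0.0737 and 0.0998), the reactive astrocyte list without mouse 686 (adjusted p = 0.0804), the endothelial and pericyte list without any 1 of mice 684, 707 and 735 (adjusted p from 0.0526 to 0.0737) and the complement list without mouse 686 or 722 (adjusted p = 0.0848 and 0.118).

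The same days were compared on the PLX5622 diet to see the injury with few microglial transcripts. At 1 day after TBI, 54 genes were higher and 2 lower than in naive PLX5622 mice, with 146 at an unadjusted p under 0.05. Gfap rose by 3.10 ± 0.56 in 8 of 8 mice (adjusted p = 1.4e-04), from 446 ± 182 (n = 6) to 3343 ± 1184 normalised counts (n = 8). Lox rose by 2.92 ± 0.34, Cd44 by 2.55 ± 0.44 and Hmox1 by 2.28 ± 0.39, each in 8 of 8 mice. Ccr2, the chemokine receptor of monocytes, rose by 1.89 ± 0.49 (8 of 8 mice), Cd68 by 1.30 ± 0.32 (8 of 8 mice) and Mmp19, a matrix metalloprotease, by 1.72 ± 0.31. Osmr, the oncostatin M receptor (1.34 ± 0.30), the interleukin 1 receptor Il1r1 (1.19 ± 0.23), Stat3 (1.10 ± 0.22) and Nes, an intermediate filament of progenitors and reactive astrocytes (1.18 ± 0.23), rose too. The 2 lower genes were Cd34, a surface protein of endothelium and progenitors (-0.58 ± 0.16, 8 of 8 mice), and Dcx, doublecortin of young neurons (-0.44 ± 0.13, 7 of 8 mice). P2ry12 (0.46 ± 0.26), Cx3cr1 (0.54 ± 0.33), Csf1r (0.30 ± 0.36) and Tmem119 (0.44 ± 0.18) were not called. Itgam, given for description, was called (1.39 ± 0.45, 7 of 8 mice, adjusted p = 0.046), but not in 6 alternatives (adjusted p from 0.0515 to 0.113) or without any 1 of mice 688, 693, 698, 705, 713, 719, 725, 731, 736 and 740 (adjusted p from 0.0695 to 0.152).

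Members of the reactive astrocyte list rose as a set (median log2 fold change 1.14, 8 of 8 mice, adjusted p = 1.6e-09, adjusted p = 0.0354 with an estimated correlation). Of its 10 measured members, 7 were higher, 0 lower and 3 not called, and 8 higher and 0 lower adjusted over the list alone. As a set, inflammatory cytokine and NF-kB genes rose (median log2 fold change 0.52, 8 of 8 mice, adjusted p = 3.4e-04, adjusted p = 0.574 with an estimated correlation). Among the 37 members measured, 11 were higher, 0 lower and 26 not called, and 16 higher and 0 lower adjusted over the list alone. Within extraction batches 1, 2 and 3 Gfap differed by 2.10, 2.46 and 3.92, Cd44 by 1.08, 3.11 and 3.18 and Lox by 1.89, 3.13 and 3.40. DESeq2 called 64 genes and edgeR 65, and the count was 32 without mouse 713, 33 without mouse 719 and 37 without mouse 731. Cd34 was not called without mouse 736 (adjusted p = 0.0635), nor Dcx without any 1 of mice 698, 703, 705, 711, 713, 719 and 736 (adjusted p from 0.0508 to 0.0817) or with no covariate (adjusted p = 0.0662).

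At 7 days on PLX5622, 12 genes were higher and 0 lower than in naive PLX5622 mice (limma, with 90 higher and 6 lower at an unadjusted p under 0.05, 29 genes called by DESeq2 and 6 by edgeR). Gfap rose by 2.55 ± 0.54 in 9 of 9 mice (adjusted p = 0.0052). C1qb rose by 2.39 ± 0.52 and C1qa by 2.30 ± 0.48, and Cx3cr1 by 1.67 ± 0.32 (9 of 9 mice, adjusted p = 0.00256). Genes of astrocytes were among those called: Aqp4, the water channel of astrocyte endfeet (1.15 ± 0.25), and Gja1, the gap junction protein connexin 43 (0.71 ± 0.19). Lox rose by 1.36 ± 0.32 and Serpinf1, a secreted neurotrophic serpin, by 0.98 ± 0.24.  The microglia list rose (median log2 fold change 0.66, 9 of 9 mice, adjusted p = 6.8e-08, adjusted p = 0.201 with an estimated correlation). Of its 23 measured members, 3 were higher, 0 lower and 20 not called, and 8 higher and 0 lower adjusted over the list alone. The complement list rose (median log2 fold change 1.37, 9 of 9 mice, adjusted p = 3.7e-06, adjusted p = 0.0568 with an estimated correlation). Among the 8 members measured, 2 were higher, 0 lower and 6 not called, and 6 higher and 0 lower adjusted over the list alone. Both called are also in the microglia list, and the 3 members outside it had a median of 0.38. As a set, astrocyte genes rose (median log2 fold change 0.37, 9 of 9 mice, adjusted p = 8.0e-04, adjusted p = 0.201 with an estimated correlation). Of its 7 measured members, 2 were higher, 0 lower and 5 not called, and 4 higher and 0 lower adjusted over the list alone. As a set, reactive astrocyte genes rose (median log2 fold change 0.48, 9 of 9 mice, adjusted p = 8.0e-04, adjusted p = 0.271 with an estimated correlation). Among the 10 members measured, 1 was higher, 0 lower and 9 not called, and 2 higher and 0 lower adjusted over the list alone. The oxidative stress defence list rose (median log2 fold change 0.19, 9 of 9 mice, adjusted p = 0.00578, adjusted p = 0.311 with an estimated correlation). Of its 12 measured members, 1 was higher (Cybb, of the phagocyte oxidase), 0 lower and 11 not called, and 4 and 0 adjusted over the list alone.

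For the inflammatory cytokine and NF-kB list the test gave a rise (median log2 fold change 0.30, 8 of 9 mice, adjusted p = 0.00727, adjusted p = 0.383 with an estimated correlation). As a set, interferon response and antigen presentation genes rose (median log2 fold change 0.65, 9 of 9 mice, adjusted p = 0.0123, adjusted p = 0.311 with an estimated correlation). The activity-regulated and CREB list ranked below other panel genes (median log2 fold change -0.08, 7 of 9 mice, adjusted p = 7.1e-05, adjusted p = 0.201 with an estimated correlation). The GABA and interneuron list ranked below other panel genes (median log2 fold change -0.02, 6 of 9 mice, adjusted p = 0.0179, adjusted p = 0.311 with an estimated correlation). The pan-neuronal list ranked below other panel genes (median log2 fold change -0.03, 8 of 9 mice, adjusted p = 0.0242, adjusted p = 0.285 with an estimated correlation). The synaptic vesicle and release list ranked below other panel genes (median log2 fold change 0.02, 5 of 9 mice, adjusted p = 0.0242, adjusted p = 0.383 with an estimated correlation). Its median had the sign opposite to that of the test (mean -0.03). In these 6 lists limma called 0 members, with at most 1 per list adjusted over the list alone, at most 10 in one direction at an unadjusted p under 0.05, at most 2 called by DESeq2 and 0 by edgeR. Within extraction batches 1, 2 and 3 at 7 days on PLX5622, Gfap differed by 1.82, 0.97 and 3.68, C1qb by 0.99, 0.51 and 3.67 and the microglia list mean by 0.30, 0.65 and 1.18. The count of genes was 6 without mouse 709 or 734, 7 without 713 or 729, 20 without 694 and 23 without 723. Serpinf1 was not called without any 1 of mice 709 and 734 (adjusted p from 0.0548 to 0.0823), Gja1 without any 1 of mice 687, 690, 698, 709, 713, 729, 731, 734 and 736 (adjusted p from 0.0562 to 0.137) or with no covariate (adjusted p = 0.0925), and Lox with no covariate (adjusted p = 0.0701). At 7 days on PLX5622, camera no longer called the pan-neuronal list without any 1 of mice 698, 705, 709 and 731 (adjusted p from 0.0569 to 0.0653), the synaptic vesicle and release list without any 1 of mice 698, 705 and 709 (adjusted p from 0.0583 to 0.0832), the inflammatory cytokine and NF-kB list without mouse 705 or 709 (adjusted p = 0.0694 and 0.0633) and the interferon response and antigen presentation list without mouse 705 or 709 (adjusted p = 0.0588 and 0.0766).

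At 30 days on PLX5622, 18 genes were higher and 0 lower than in naive PLX5622 mice (limma, with 86 higher and 2 lower at an unadjusted p under 0.05, 26 genes called by DESeq2 and 16 by edgeR), 13 of them in the microglia list. C1qb rose by 3.65 ± 0.56, from 10.8 ± 9.37 (n = 6) to 192 ± 158 normalised counts (n = 7), against 469 ± 37.1 in naive vehicle mice. C1qa rose by 3.44 ± 0.51 and C1qc by 2.80 ± 0.61. Cx3cr1 rose by 2.48 ± 0.34 in 7 of 7 mice (adjusted p = 1.5e-06), Trem2 by 1.65 ± 0.37, Cd68 by 1.53 ± 0.32, Csf1r by 1.44 ± 0.37 and P2ry12 by 1.24 ± 0.27, while Tmem119 was not called (0.32 ± 0.18, adjusted p = 0.532). Itgam had 2.54 ± 0.46. Gfap rose by 2.62 ± 0.57 in 7 of 7 mice (adjusted p = 0.00316) and Aqp4 by 1.00 ± 0.27. The microglia list rose (median log2 fold change 1.24, 7 of 7 mice, adjusted p = 1.3e-27, adjusted p = 8.6e-04 with an estimated correlation). Among the 23 members measured, 13 were higher, 0 lower and 10 not called, and 19 higher and 0 lower adjusted over the list alone. The complement list rose (median log2 fold change 2.08, 6 of 7 mice, adjusted p = 2.3e-11, adjusted p = 8.6e-04 with an estimated correlation). Of its 8 measured members, 5 were higher, 0 lower and 3 not called, and 6 higher and 0 lower adjusted over the list alone. The 3 complement members outside the microglia list had a median of 0.59.

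The reactive astrocyte list rose (median log2 fold change 0.49, 7 of 7 mice, adjusted p = 0.00599, adjusted p = 0.516 with an estimated correlation). Among the 10 members measured, 1 was higher, 0 lower and 9 not called, and 4 higher and 0 lower adjusted over the list alone. The astrocyte list rose (median log2 fold change 0.42, 6 of 7 mice, adjusted p = 0.0136, adjusted p = 0.51 with an estimated correlation). Of its 7 measured members, 1 was higher, 0 lower and 6 not called, and 4 higher and 0 lower adjusted over the list alone. The oxidative stress defence list rose (median log2 fold change 0.22, 7 of 7 mice, adjusted p = 0.0341, adjusted p = 0.577 with an estimated correlation). Of 12 members measured, 1 was higher (Ncf1, of the phagocyte oxidase), 0 lower and 11 not called, and 3 and 0 adjusted over the list alone. The activity-regulated and CREB list ranked below other panel genes (median log2 fold change 0.05, 5 of 7 mice, adjusted p = 0.0341, adjusted p = 0.586 with an estimated correlation). Its median had the sign opposite to that of the test (mean -0.03). Camera placed the GABA and interneuron list below other panel genes (median log2 fold change 0.00, 3 of 7 mice, adjusted p = 0.0486, adjusted p = 0.577 with an estimated correlation). Its median and mean had the sign opposite to that of the test (mean 0.02). In these 2 lists limma called 0 members, with 0 per list adjusted over the list alone, at most 1 in one direction at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by edgeR. Within extraction batches 1, 2 and 3 at 30 days on PLX5622, the microglia list mean differed by 1.12, 1.53 and 1.53, Gfap by 2.11, 1.97 and 3.09 and C1qb by 3.71, 1.95 and 4.22. The count of genes was 10 without mouse 727. Csf1r was not called without any 1 of mice 713, 715, 721, 727 and 736 (adjusted p from 0.0674 to 0.0958), nor Aqp4 without any 1 of mice 690, 700, 713, 715, 721, 727, 731 and 736 (adjusted p from 0.05 to 0.137) or with no covariate (adjusted p = 0.053). At 30 days on PLX5622, camera no longer called the astrocyte list without mouse 727 or 736 (adjusted p = 0.0524 and 0.0557), the reactive astrocyte list without mouse 733 (adjusted p = 0.0724), the GABA and interneuron list without any 1 of mice 698, 705, 708, 713, 715, 727, 731, 733 and 736 (adjusted p from 0.0524 to 0.178), the activity-regulated and CREB list without any 1 of mice 685, 705, 713, 715, 733 and 736 (adjusted p from 0.0531 to 0.194) and the oxidative stress defence list without any 1 of mice 713, 727, 731 and 733 (adjusted p from 0.051 to 0.0904).

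The diets were then compared at each day after TBI. At 1 day, 32 genes were lower on PLX5622 and 1 was higher, with 99 at an unadjusted p under 0.05 (24 higher and 75 lower). C1qb changed by -5.79 ± 0.55, Csf1r by -4.18 ± 0.37, Fcrls by -4.54 ± 0.48 and P2ry12 by -3.79 ± 0.26, each in 8 of 8 mice. Ccl12 changed by -4.42 ± 0.54 (adjusted p = 7.2e-09, 8 of 8 mice). Cxcl12, a chemokine made by stromal and endothelial cells, was the higher gene (0.59 ± 0.17, 7 of 8 mice, adjusted p = 0.0251), and Gfap was not called (0.57 ± 0.57, adjusted p = 0.744). The microglia list fell (median log2 fold change -2.08, 8 of 8 mice, adjusted p = 4.8e-53, adjusted p = 2.9e-06 with an estimated correlation). Of its 23 measured members, 0 were higher, 19 lower and 4 not called, and 0 higher and 20 lower adjusted over the list alone. The complement list fell (median log2 fold change -3.15, 8 of 8 mice, adjusted p = 1.3e-09, adjusted p = 0.00226 with an estimated correlation). Among the 8 members measured, 0 were higher, 5 lower and 3 not called, and 0 higher and 5 lower adjusted over the list alone. The 3 complement members outside the microglia list had a median of 0.19, the opposite sign. DESeq2 called 35 genes and edgeR 39. Cxcl12 was not called without any 1 of mice 693, 697, 704 and 711 (adjusted p from 0.0503 to 0.12), with no covariate (adjusted p = 0.0674) or with the extraction batch as covariate (adjusted p = 0.0584, range 0.0121 to 0.0674 over 6 alternatives).  Centring on the sample median gave 12 higher and 30 lower.

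At 7 days, 33 genes were lower on PLX5622 and 0 higher (limma, with 13 higher and 56 lower at an unadjusted p under 0.05, 41 genes called by DESeq2 and 41 by edgeR). P2ry12 changed by -4.04 ± 0.24, Cx3cr1 by -3.59 ± 0.31 and C1qb by -3.86 ± 0.50. Ccl12 changed by -2.15 ± 0.50 (9 of 9 mice) and Nlrp3, an inflammasome sensor, by -1.28 ± 0.32 (9 of 9 mice). Gfap was not called (1.14 ± 0.52, adjusted p = 0.426). As a set, microglia genes fell (median log2 fold change -2.05, 9 of 9 mice, adjusted p = 3.3e-63, adjusted p = 2.9e-07 with an estimated correlation). Of its 23 measured members, 0 were higher, 19 lower and 4 not called, and 0 higher and 20 lower adjusted over the list alone. The complement list fell (median log2 fold change -2.73, 9 of 9 mice, adjusted p = 6.9e-09, adjusted p = 0.00375 with an estimated correlation). Among the 8 members measured, 0 were higher, 5 lower and 3 not called, and 0 higher and 5 lower adjusted over the list alone. The 3 complement members outside the microglia list had a median of 0.29, the opposite sign. The inflammatory cytokine and NF-kB list ranked below other panel genes (median log2 fold change -0.08, 8 of 9 mice, adjusted p = 0.043, adjusted p = 0.952 with an estimated correlation). Of its 37 measured members, 0 were higher, 5 lower and 32 not called, and 0 higher and 6 lower adjusted over the list alone. As a set, interferon response and antigen presentation genes fell (median log2 fold change -0.91, 8 of 9 mice, adjusted p = 0.00969, adjusted p = 0.594 with an estimated correlation). Among the 5 members measured, 0 were higher, 0 lower and 5 not called, and 0 higher and 3 lower adjusted over the list alone (limma, where 0 lay higher and 4 lower at an unadjusted p under 0.05, with 2 called by DESeq2 and 2 by edgeR). Between diets at 7 days, camera no longer called the inflammatory cytokine and NF-kB list without any 1 of mice 686, 694, 702, 717, 723, 729 and 739 (adjusted p from 0.0553 to 0.515) and the interferon response and antigen presentation list without mouse 686 (adjusted p = 0.217).

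At 30 days, 20 genes were lower on PLX5622 and 1 was higher, with 67 at an unadjusted p under 0.05. P2ry12 changed by -3.80 ± 0.28, Csf1r by -3.28 ± 0.39, Cx3cr1 by -2.95 ± 0.36 and Tmem119 by -1.89 ± 0.19, each in 7 of 7 mice, and C1qa by -2.26 ± 0.54. Gfap was the higher gene (2.15 ± 0.60, 6 of 7 mice, adjusted p = 0.0321), at 3312 ± 2474 normalised counts on PLX5622 (n = 7) and 874 ± 972 on vehicle (n = 5). The microglia list fell (median log2 fold change -1.47, 7 of 7 mice, adjusted p = 1.6e-28, adjusted p = 0.00134 with an estimated correlation). Of its 23 measured members, 0 were higher, 13 lower and 10 not called, and 0 higher and 17 lower adjusted over the list alone. As a set, complement genes fell (median log2 fold change -1.67, 7 of 7 mice, adjusted p = 0.0123, adjusted p = 0.419 with an estimated correlation). Among the 8 members measured, 0 were higher, 4 lower and 4 not called, and 0 higher and 4 lower adjusted over the list alone. The 3 complement members outside the microglia list had a median of 0.42, the opposite sign. As a set, reactive astrocyte genes rose (median log2 fold change 0.24, 6 of 7 mice, adjusted p = 0.00347, adjusted p = 0.419 with an estimated correlation). Of its 10 measured members, 1 was higher, 0 lower and 9 not called, and 2 higher and 0 lower adjusted over the list alone. The astrocyte list rose (median log2 fold change 0.24, 4 of 7 mice, adjusted p = 0.00491, adjusted p = 0.419 with an estimated correlation). Members of the oligodendrocyte and myelin list rose as a set (median log2 fold change 0.11, 6 of 7 mice, adjusted p = 0.00347, adjusted p = 0.849 with an estimated correlation). In these 2 lists limma called 0 members, with 0 per list adjusted over the list alone, at most 2 in one direction at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by edgeR.

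The Gfap difference between diets at 30 days was 3.38, 2.36 and -0.03 within extraction batches 1, 2 and 3, so it did not hold in batch 3, and vehicle had 1, 3 and 1 mice in them. Its call was lost without any 1 of mice 684, 700, 707, 715, 721, 722, 727 and 728 (adjusted p from 0.0566 to 0.189), with the extraction batch as covariate (adjusted p = 0.0538) and with cartridge and extraction batch together (adjusted p = 0.0578, range 0.0129 to 0.0578 over 6 alternatives). The count of genes at 30 days was 13 without mouse 707. Between diets at 30 days, camera no longer called the astrocyte list without mouse 727 (adjusted p = 0.0751), the oligodendrocyte and myelin list without mouse 684 (adjusted p = 0.557) and the complement list without any 1 of mice 685, 707, 708 and 716 (adjusted p from 0.0505 to 0.103). Within extraction batches 1, 2 and 3 the microglia list mean differed between diets by -2.76, -2.52 and -2.65 at 1 day, -3.31, -2.47 and -1.76 at 7 days and -1.33, -1.37 and -2.08 at 30 days.

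Whether the response to injury differed between diets was tested as an interaction of diet and injury, where higher and lower refer to the log2 fold change on PLX5622 against that on vehicle. At 1 day 1 gene was lower and 0 were higher (limma, with 38 higher and 4 lower at an unadjusted p under 0.05, 1 called by DESeq2 and 1 by edgeR). It was Ccl12 (-3.70 ± 0.78, adjusted p = 0.0142), which changed by 3.15 ± 0.57 on vehicle and -0.55 ± 0.53 on PLX5622, and its call was lost without any 1 of mice 711, 726 and 736 (adjusted p from 0.0572 to 0.0728). For Gfap the interaction was 0.27 ± 0.82 (adjusted p = 0.974). Camera placed the interferon response and antigen presentation list below other panel genes (median interaction -0.58, adjusted p = 0.0212, adjusted p = 0.903 with an estimated correlation). The list mean went from 4.70 to 5.54 on vehicle and from 4.47 to 4.82 on PLX5622. In this list limma called 0 members, with 0 adjusted over the list alone, 0 in its direction at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by edgeR. Calls made at 1 day in one diet alone are not shown to differ between diets except for Ccl12. In the 1 day interaction, camera no longer called the interferon response and antigen presentation list without any 1 of mice 696, 697, 706, 720 and 726 (adjusted p from 0.0534 to 0.233). At 7 days, limma called 0 of the 799 genes, with 34 higher and 0 lower at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by edgeR. The interaction of Gfap was 0.85 ± 0.78 (adjusted p = 0.856), of C1qb 1.74 ± 0.75 (adjusted p = 0.812) and of Cx3cr1 1.53 ± 0.46 (adjusted p = 0.609), so these are not shown to differ between diets. The interferon response and antigen presentation list ranked below other panel genes (median interaction -0.37, adjusted p = 2.5e-04, adjusted p = 0.404 with an estimated correlation). Its mean went from 4.70 to 6.01 on vehicle and from 4.47 to 5.21 on PLX5622. Camera placed the inflammatory cytokine and NF-kB list below other panel genes (median interaction 0.06, adjusted p = 0.00614, adjusted p = 0.799 with an estimated correlation). Its median had the sign opposite to that of the test (mean -0.03). Camera placed the oxidative stress defence list above other panel genes (median interaction 0.29, adjusted p = 0.029, adjusted p = 0.799 with an estimated correlation). In these 3 lists limma called 0 members, with 0 per list adjusted over the list alone, at most 2 in one direction at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by edgeR. In the 7 day interaction, camera no longer called the inflammatory cytokine and NF-kB list without mouse 686 or 690 (adjusted p = 0.217 and 0.0847), the interferon response and antigen presentation list without mouse 686 (adjusted p = 0.0782) and the oxidative stress defence list without any 1 of mice 686, 695, 701, 724, 730 and 731 (adjusted p from 0.0536 to 0.11).

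At 30 days the interaction was called higher for 3 genes and lower for 0 (limma, with 26 higher and 0 lower at an unadjusted p under 0.05, 5 called by DESeq2 and 5 by edgeR). They were Cx3cr1 (2.18 ± 0.49, adjusted p = 0.0398), C1qa (3.05 ± 0.74, adjusted p = 0.043) and C1qb (3.29 ± 0.81, adjusted p = 0.043). Naive PLX5622 means of all 3 lay under background, and in normalised counts the change on PLX5622 minus that on vehicle was -12.3 ± 15.9, 7.35 ± 67.8 and 14.8 ± 95.4 (SE). For Gfap it was 1.86 ± 0.83 (adjusted p = 0.994), for Csf1r 1.09 ± 0.54 and for P2ry12 1.02 ± 0.39, none called. Camera placed the microglia list above other panel genes (median interaction 1.02, adjusted p = 4.0e-17, adjusted p = 0.0173 with an estimated correlation). Among the 23 members measured, 3 were higher, 0 lower and 20 not called, and 7 higher and 0 lower adjusted over the list alone. Camera placed the complement list above other panel genes (median interaction 1.59, adjusted p = 6.3e-11, adjusted p = 0.00183 with an estimated correlation). Of its 8 measured members, 2 were higher, 0 lower and 6 not called, and 4 higher and 0 lower adjusted over the list alone. The 2 called are also in the microglia list, and the 3 members outside it had a median of 0.64. Camera placed the reactive astrocyte list above other panel genes (median interaction 0.50, adjusted p = 0.00681, adjusted p = 0.692 with an estimated correlation). The oligodendrocyte and myelin list ranked above other panel genes (median interaction 0.27, adjusted p = 0.00681, adjusted p = 0.692 with an estimated correlation). Camera placed the endothelial and pericyte list below other panel genes (median interaction -0.08, adjusted p = 0.0424, adjusted p = 0.692 with an estimated correlation). In these 3 lists limma called 0 members, with 0 per list adjusted over the list alone, at most 2 in one direction at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by edgeR. The count of genes was 0 without any 1 of mice 684, 695, 700, 705, 706, 714, 715, 721, 722, 727, 728, 731, 737 and 742, 1 without any 1 of mice 691, 713, 732 and 736 and 5 without mouse 708. Of 25 runs with 1 mouse left out, the call was lost in 14 for Cx3cr1, 20 for C1qa and 20 for C1qb. In the 30 day interaction, camera no longer called the oligodendrocyte and myelin list without any 1 of mice 684, 695 and 715 (adjusted p from 0.0524 to 0.454) and the endothelial and pericyte list without any 1 of mice 684, 690, 695, 700, 707, 708, 714, 721, 731, 732, 733 and 736 (adjusted p from 0.057 to 0.26).

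Across the 799 genes, which are not independent replicates, the log2 fold changes after TBI on vehicle and on PLX5622 had a Pearson r of 0.66 and a Spearman rho of 0.54 at 1 day, 0.56 and 0.41 at 7 days, and 0.38 and 0.39 at 30 days, with no library in both comparisons. Leaving out 1 mouse gave r as low as 0.60 at 1 day (mouse 726), 0.48 at 7 days (mouse 686) and 0.20 at 30 days (mouse 716). Of the 18 genes called at 1 day on vehicle, 17 had the same sign on PLX5622 and 10 were also called there. These 10 were higher genes, of 15 and 54, where independent lists of those sizes would share 1.01, and the 3 and 2 lower genes shared 0, where 0.0075 would be shared. Gfap, Cd44, Lox, Hmox1, Msn and Tnfrsf1a were among the 10. All 56 genes called at 1 day on PLX5622 had the same sign on vehicle, as did 11 of 12 at 7 days and 18 of 18 at 30 days.

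**Figure D3:**
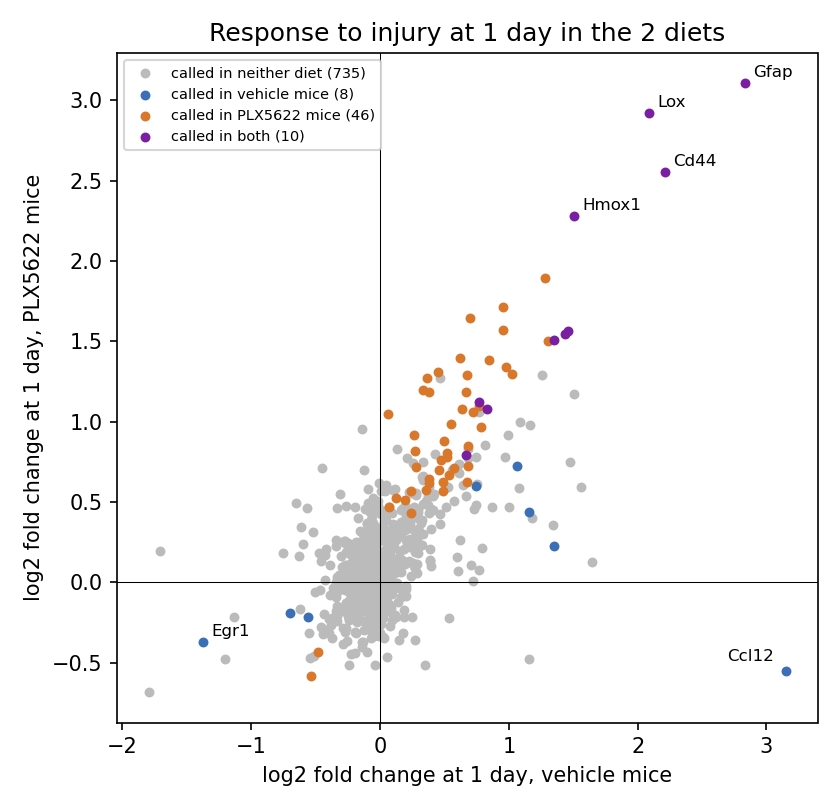
Log2 fold change of each of the 799 genes 1 day after TBI against naive mice on vehicle (horizontal axis) and on PLX5622 (vertical axis), where points are genes and colours show where a gene was called. Called in both diets were 10 genes, on vehicle alone 8, on PLX5622 alone 46 and in neither 735.

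Lists not called in any of the 15 comparisons were 7. Their lowest adjusted p was 0.0545 for apoptosis and cell stress (PLX5622, 1 day), 0.0669 for neurodegeneration-associated genes (vehicle, 7 to 30 days) and 0.121 for growth factors and vascular remodelling (vehicle, 7 days). For lysosome and autophagy it was 0.125 (between diets, 1 day), for border macrophages and infiltrating leukocytes 0.178 (vehicle, 7 days), for the panel's reference genes 0.258 (PLX5622, 30 days) and for axon guidance and cytoskeleton 0.265 (vehicle, 7 to 30 days). Their medians there were 0.22, 0.17, -0.02, -0.15, 0.14, 0.01 and 0.15, in that order.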

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

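Chosen after the result was seen were the tests of border macrophages, of time on the diet, of the choice of region and of normalised counts, while those of batch and depth were chosen before. In groups of 4 to 10 mice, 13 of 312 tests (17 genes, 21 lists and total counts) found a mouse far from the others by Dixon's ratio, and chance gives about 1 in 20. Among single genes, P2ry12 was lowest in mouse 726 (vehicle, 1 day) at a log2 value of 7.04, Aif1 highest in mouse 707 (vehicle, 30 days) at 4.41 and Gfap lowest in mouse 713 (PLX5622, naive) at 7.20. C1qa was listed at 0 in mouse 698 (PLX5622, naive), Lox was lowest in mouse 694 (PLX5622, 7 days) at 3.19 and Hmox1 highest in mouse 714 (vehicle, naive) at 5.09.

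Among list means at 30 days on PLX5622, mouse 733 was highest for border macrophages and leukocytes at 4.19 and lowest for oligodendrocytes and myelin at 6.89. Mouse 715 was highest there for endothelium and pericytes at 7.52 and mouse 685 lowest for activity-regulated and CREB genes at 9.265. In naive vehicle mice, mouse 706 was highest for synaptic vesicles and release at 10.85 and mouse 737 lowest for axon guidance and cytoskeleton at 7.89. Mouse 716 was highest for lysosome and autophagy at 8.17 among vehicle mice at 30 days.

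On the log2 scale, the response to injury differed between diets by the interaction test for Ccl12 at 1 day (-3.70) and, at 30 days, for C1qa (3.05), C1qb (3.29), Cx3cr1 (2.18), the microglia list (median 1.02) and the complement list (median 1.59). In normalised counts, the differences of the 3 genes at 30 days lay within 1 SE of 0, and that of Ccl12 was -84.4 ± 28.7 (SE).

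The microglia list mean rose at 30 days on PLX5622 by 1.43 ± 0.25 SE (n = 7 and 6). Batch and depth are argued against as the whole cause: with cartridge and extraction batch in the fit the rise was 1.45 ± 0.25, within extraction batches it was 1.12, 1.53 and 1.53, and with total counts in the fit 1.44 ± 0.25. Border macrophages or blood leukocytes in place of microglia stay open: the border list moved by 0.25 ± 0.19, a difference of 1.18 ± 0.29 between the lists, but 4 of its 6 genes lay under background in all 8 groups, and genes near the floor exclude nothing, while Ccr2, picked after its value was seen, had 1.22 ± 0.50 (adjusted p = 0.262). Longer time on the diet, and the choice of the region by CD11b, cannot be told apart from injury, because there is 1 PLX5622 group without injury. A return of microglia on the diet may explain the rise, a hypothesis that none of these tests reached.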

How the results depend on the processing

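Chosen after the data were seen were edgeR, the weight per group, the fits without 3 shallow libraries (mice 693, 698 and 701) and the list tests with each mouse left out. No paired analysis was possible, as no 2 groups share a mouse. Over the 6 alternatives of covariate, scaling and low values, 389 values of named genes gave 2171 results that kept direction and side of the threshold, 40 that fell short of it, 12 that passed it, 1 that moved and 0 that reversed. For the 68 list calls, over the settings run on lists other than 1 mouse left out, these were 651 kept, 98 short of the threshold, 3 moved and 6 reversed. The cause was not tested for any change below unless it is given.

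The calls reported were 18 (vehicle 1 day), 0 (vehicle 7 days), 0 (vehicle 30 days), 56 (PLX5622 1 day), 12 (PLX5622 7 days), 27 (diets without injury), 33 (diets at 1 day), 33 (diets at 7 days), 0 (1 to 7 days), 0 (7 to 30 days), 1 (interaction at 1 day) and 3 (interaction at 30 days), with unadjusted counts in the report. Counts outside 1.5 times these were as follows. Centring on reference genes gave 28 (vehicle 1 day), 3 (vehicle 7 days), 1 (vehicle 30 days) and 1 (1 to 7 days), and centring on the sample median 4 (vehicle 7 days), 1 (vehicle 30 days) and 1 (1 to 7 days). With genes of mean under 32.4 left out, so that fewer genes were tested, counts were 9 (vehicle 1 day), 1 (vehicle 30 days), 34 (PLX5622 1 day), 16 (diets without injury), 15 (diets at 1 day), 17 (diets at 7 days) and 0 (interaction at 1 day). In fits on the mice of the compared groups alone, counts were 65 (vehicle 1 day), 33 (PLX5622 1 day), 3 (PLX5622 7 days), 5 (1 to 7 days) and 2 (interaction at 1 day). DESeq2 called 38 (vehicle 1 day), 10 (vehicle 7 days), 1 (vehicle 30 days), 29 (PLX5622 7 days), 15 (1 to 7 days), 2 (7 to 30 days) and 5 (interaction at 30 days). By edgeR there were 40 (vehicle 1 day), 9 (vehicle 7 days), 6 (PLX5622 7 days), 9 (1 to 7 days), 4 (7 to 30 days) and 5 (interaction at 30 days). A weight per group gave 31 (vehicle 1 day), 4 (vehicle 7 days), 1 (vehicle 30 days), 34 (PLX5622 1 day) and 7 (PLX5622 7 days), and leaving out the shallow libraries 36 (vehicle 1 day), 1 (vehicle 30 days) and 13 (1 to 7 days). With no covariate the counts were 37 (PLX5622 1 day), 6 (PLX5622 7 days) and 1 (interaction at 30 days), and with the extraction batch 1 (vehicle 7 days), 7 (PLX5622 7 days) and 1 (interaction at 30 days). A pseudocount of 10 gave 2 (vehicle 7 days), 3 (PLX5622 7 days) and 0 (interaction at 30 days), eBayes without a trend 7 (PLX5622 7 days) and 0 (interaction at 30 days) and robust eBayes 1 (interaction at 30 days). Camera has no robust option.

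Splits of higher against lower moved with the scaling or the tool: at 1 day on vehicle 15 and 3 became 16 and 7 (sample median) or 18 and 10 (reference genes), at 1 day on PLX5622 54 and 2 became 37 and 10 (sample median) or 49 and 16 (edgeR), and between diets at 1 day 1 and 32 became 12 and 30 (sample median). Centring on the sample median moved the median of all genes by up to 0.17, between diets without injury. The list calls numbered 68 and were 14 with an estimated correlation, and from 53 to 76 in the other settings. Without its members in the microglia list, the complement list reversed to -0.033 (vehicle 1 day), -0.016 (vehicle 7 days), 0.19 (diets at 1 day), 0.29 (diets at 7 days) and 0.42 (diets at 30 days). The inflammatory list in the interaction at 7 days reversed to 0.24 with low genes left out, which raised r between diets to 0.78 at 1 day and 0.71 at 7 days.

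With 1 mouse left out in turn, counts ran as follows at 1, 7 and 30 days. On vehicle they were 9 to 28, 0 to 8 and 0 to 1. On PLX5622 they were 32 to 66, 6 to 23 and 10 to 23. Between diets they were 26 to 34, 27 to 39 and 13 to 22, and 25 to 30 without injury. In the interactions they were 0 to 1, 0 to 0 and 0 to 5. From 1 to 7 days they were 0 to 11 and from 7 to 30 days 0 to 1. Called in every run were 7 genes (vehicle 1 day), 29, 6 and 9 (PLX5622), 25, 27 and 13 (diets) and 25 (diets without injury). Shallow libraries limit low genes most: 1 count is worth more there, and genes near the background cannot show a fall.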

Other observations

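Chosen after the result was seen were the tests of the interferon list, of the extraction batch and of what splits follow. The other tests in this part were chosen before. The SD of Gfap between mice on the log2 scale, not tested between groups, was 0.41 in naive vehicle mice, 0.69 at 1 day, 1.31 at 7 days and 1.40 at 30 days, and on PLX5622 0.77 (with mouse 713 lowest), 0.53, 1.55 and 1.33. Aif1, a cytoplasmic marker of microglia, was not called in any of the 15 comparisons (between diets without injury -0.30 ± 0.25), at 15.4 ± 5.01 normalised counts in naive vehicle mice, near the background of 15.4.

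Gfap and the microglia list mean varied together across mice of 4 groups by Pearson's r, but in none by the adjusted p of Spearman's rho, in 7 relations tested with exact permutation tests. At 30 days on PLX5622 (n = 7) Pearson's r was 0.95 (exact permutation p = 0.00198, adjusted p = 0.0139) and Spearman's rho 0.857 (exact permutation p = 0.0238, adjusted p = 0.0556), and r was 0.841 without the 2 mice farthest from the median. Adjusted exact permutation p of r and of rho was 0.0375 and 0.0556 at 7 days on PLX5622 (r 0.766, rho 0.783). It was 0.0375 and 0.0556 at 7 days on vehicle (r 0.865, rho 0.893) and 0.0389 and 0.18 at 1 day on vehicle (r 0.88, rho 0.771). In the other groups r was 0.227 (naive, vehicle), 0.472 (naive, PLX5622) and -0.132 (PLX5622, 1 day). At 30 days on PLX5622 r was 0.917 with the cartridge effect taken off and 0.967 with depth, which argues against each as the whole cause. The extraction batch correction moved batch 2 mice alone, so its r of 0.949 cannot test the batch. Batches of 2, 3 and 2 mice give no r of their own. No biological explanation was tested.

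The interferon list at 7 days on vehicle was called although limma called 0 of its 5 genes. Runs with 1 mouse left out (highest adjusted p 2.5e-10) used the preset correlation alone. Mice 686, 702, 710, 730 and 735, not 718 and 724, had list means (5.47 to 7.86) above all naive vehicle mice (to 4.95). A single mouse is argued against, as is correlation among members (adjusted p = 0.00278 with an estimated correlation). A response to the injury stays open as a hypothesis. Whether it depends on microglia stays open too: the list also rose at 7 days on PLX5622 (median 0.65, 9 of 9 mice, adjusted p = 0.0123, adjusted p = 0.311 with an estimated correlation), and the call in the interaction (median -0.37, adjusted p = 2.5e-04, adjusted p = 0.404 with an estimated correlation) was lost without mouse 686 (adjusted p = 0.0782).

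Splits of the same mice into groups of the same sizes, 100 drawn with a fixed seed and the real one included, gave as many called genes as the real split in 1 of 100 (vehicle 1 day, real 18, highest other 3), 4 of 100 (PLX5622 1 day, real 56, highest other 100), 2 of 100 (PLX5622 7 days, real 12, highest other 23), 3 of 100 (PLX5622 30 days, real 18, highest other 21), 1 of 100 (diets without injury, real 27, highest other 21), 4 of 100 (diets at 1 day, real 33, highest other 54), 2 of 100 (diets at 7 days, real 33, highest other 47), 1 of 100 (diets at 30 days, real 21, highest other 13), 8 of 100 (interaction at 1 day, real 1, highest other 57) and 1 of 100 (interaction at 30 days, real 3, highest other 0). Where limma called 0, counts at an unadjusted p under 0.05 were as large in 8 of 100 (vehicle 7 days, real 51, highest other 117), 31 of 100 (vehicle 30 days, real 29, highest other 96), 22 of 100 (1 to 7 days, real 66, highest other 179), 17 of 100 (7 to 30 days, real 71, highest other 169) and 39 of 100 (interaction at 7 days, real 34, highest other 170). Shares exceeded 0.05 for vehicle 7 and 30 days, 1 to 7 days, 7 to 30 days and the interactions at 1 and 7 days. The lower shares, unadjusted, do not exclude chance. Some other splits called several times the real count, such as 57 against 1 in the interaction at 1 day, and the cause was not found. In that split the share of injured mice was higher in the group taken as injured in both diets (by 0.42 on PLX5622, 0.38 on vehicle), and counts were nearly unrelated to how far this difference parted between diets (Spearman's rho 0.00206 over 99 splits) or to depth (0.137, and from -0.113 to 0.209 outside the interactions).

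For numbers of lists called, the splits of 100 that reached the real number are given with the real and highest other number in brackets. On vehicle at 1, 7 and 30 days they were 3 (8, 9), 3 (9, 12) and 31 (2, 6). On PLX5622 they were 51 (2, 9), 6 (11, 11) and 3 (7, 8). Between diets they were 62 (2, 6), 49 (4, 11) and 9 (5, 8), and 47 (2, 4) without injury. In the interactions they were 56 (1, 6), 51 (3, 10) and 11 (5, 9). From 1 to 7 days there were 69 (1, 11) and from 7 to 30 days 27 (6, 11). The count of lists does not measure how far a list moved, so it cannot test the fall of the microglia list between diets. In that list naive mice did not overlap (at most 3.34 on PLX5622, at least 5.61 on vehicle). The lowest shares here, 3 of 100, were unadjusted and do not exclude chance.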
